A study of Homo sapiens with 2 samples.

How the data were processed

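The libraries held transcripts of islet organoids made from H1 cells, an established human embryonic stem cell line. Such organoids contain insulin-producing cells (SC-beta cells), glucagon-producing cells (SC-alpha cells), serotonin-producing enterochromaffin cells and progenitors. Per the labels' protocols, the droplet libraries used the 10x Genomics 3' v3.1 chemistry, which counts each captured transcript once by a unique molecular identifier (UMI). The groups came from the treatment characteristic of each sample: 11 days of BMP4, a signalling protein of the TGF-beta superfamily, at 5 ng/ml, or 11 days of control treatment. The treatment protocol text is the same for both samples and names BMP4 for both, so it could not separate them. Each group had 1 library. Cells of 1 library are not replicates, so no test was made, no p-value is given, and every difference lacks a replicate check.

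The deposited values are raw UMI counts per gene and barcode, made with Cell Ranger 7.2.0 per the file headers. The submitters' processing notes name the same version and the hg38 genome build. The gene annotation and the treatment of intronic reads are not given in the sources used here. Per the labels' protocols, nuclei were taken from about 1000 aggregates of about 1000 cells each, 60000 nuclei were sorted, 16550 were loaded and the cDNA was amplified for 12 cycles. The control library had 6832 barcodes with 224446715 UMIs and the BMP4 library 9127 barcodes with 246067621 UMIs. Both tables listed the same 36601 genes. The chromosome, start and end of a gene are 1-based hg38 positions from the GENCODE version 29 annotation, in which 34616 of the 36601 gene identifiers were found.

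Before the data were examined, the filter had been set for nuclei, at 500 or more detected genes and at most 5% mitochondrial UMIs. That filter left 966 control and 1241 BMP4 barcodes, 2207 in all, of which 634 and 858 had under 2000 genes. Most gene-rich barcodes carried mitochondrial UMIs at the level of whole cells. The filter used was therefore 2000 or more genes and at most 20% mitochondrial UMIs. It was chosen from the genes and mitochondrial UMIs per barcode, before any gene was compared between the libraries. The earlier filter was kept as an alternative. The filter used kept 3836 control barcodes (56.1%) and 4654 BMP4 barcodes (51.0%). The study states 9197 cells over both libraries, without a filter in the sources used here; the files held 15959 barcodes, of which 8490 passed. Scrublet's automatic threshold, run through scanpy, marked 0 control and 1 BMP4 barcodes as doublets, 0.0215% of the latter, so it had not worked. The highest scores were removed instead, at 0.8% per 1000 barcodes kept, which took out 118 control and 173 BMP4 barcodes. The analysed cells numbered 3718 and 4481, 8199 in all.

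Counts were scaled to 10000 per cell and put on a log scale for clustering only. The 2000 most variable genes were centred and scaled within each library, reduced to 30 principal components, joined by 15 nearest neighbours and grouped with the Leiden method at resolution 1 and seed 0. Markers of 17 cell classes were fixed before the data were examined. The thresholds for using them were set after the clusters had been seen: a cluster took a name from 3 or more markers that were 2-fold above the other cells and detected in 25% of its cells. A cluster stayed unnamed where its 10 leading genes held more markers of another class, or where its median UMI count was under 1/3 of its library's with no marker of that name leading. Clusters left unnamed held 32.8% of control and 29.2% of BMP4 cells. A class was compared between libraries where each held 100 or more of its cells.

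UMIs were summed per class and library and given as CPM of that sum. Counting intervals are exact at 95%: Poisson for a level, conditional binomial for a ratio of levels and Clopper-Pearson for a share of cells. They cover counting error only, not the spread between cells, cultures or libraries. SC-beta-like cells held 22110838 UMIs in the control and 29707643 in the BMP4 library, so 3 UMIs correspond to 0.136 and 0.101 CPM. The log2 ratio was BMP4 over control with 5 CPM added to both. A gene was compared with 20 CPM and 50 UMIs or more in the higher library. Named genes followed a rule of size fixed before the data were examined. In SC-beta-like cells these were the 12 highest and 12 lowest log2 ratios, and in each other compared class the 4 highest and 4 lowest. Mitochondrial genes and genes named only by a clone were left out. A gene under 10% of its level in the class where it was highest was also left out, because free RNA in the droplets can give such levels. INS, the BMP target genes and up to 4 members of each fixed list with the largest ratios were named besides. A member that this rule also names is not reported here. 19 gene lists were fixed before the data were examined, and a list's median was placed among 10000 random lists of the same size matched on mean expression. This percentile describes these libraries and is no test. The lists covered BMP target genes, BMP pathway components, islet transcription factors, beta cell maturation, insulin secretion and exocytosis, ion channels and calcium handling, incretin and cAMP signalling, nuclear genes of oxidative phosphorylation, glycolysis, unfolded protein and stress response, immediate early genes, hypoxia, Notch and progenitor genes, Wnt targets, TGF-beta and activin targets, extracellular matrix and integrins, proliferation, other endocrine hormones and regulators, and cholesterol synthesis. Lists of clock genes and of CREB target genes were added later for the closing observations.

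The steps were tested on simulated counts for the comparison of SC-beta-like cells, with 7130 genes in the step. Of 50 genes simulated at each of 1.25-fold, 1.5-fold, 2-fold and 3-fold, 100% had intervals that excluded a ratio of 1. The median recovered log2 sizes were 0.31, 0.55, 0.94 and 1.43, which lie below the true sizes because of the added CPM. Of 6930 genes simulated without a difference, 5.05% had intervals that excluded 1. The summed count of each gene was drawn from a Poisson distribution, the model behind the intervals, so a share near 5% was built in. Spread between cells was not simulated. As a floor for the observed sizes, the cells of 1 library were split at random 20 times and the parts compared with each other.

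The alternatives were other filters, other treatments of doublets, no centring, clustering of each library on its own, clustering without genes over 2-fold apart, resolutions of 0.5 and 2, only cells with INS as the largest hormone count, TMM and median of ratios scaling, the mean over cells, thinning to 3000 UMIs per cell, 1 or 20 CPM added, and minima of 5 or 50 CPM. Added after the data were seen were the filters at 10% and 30% mitochondrial UMIs and at 500 genes, mitochondrial genes left out of the totals, each SC-beta cluster alone, an unnamed INS-rich cluster added to SC-beta, and the cell with most UMIs of a gene left out. The tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, the last for TMM factors only.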

Results

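Single-cell transcriptomes were measured in islet organoids made from H1 human embryonic stem cells and kept for 11 days with 5 ng/ml BMP4 or with control treatment. There was 1 library per group. The analysed control cells numbered 3718 and the analysed BMP4 cells 4481. The barcodes that passed the filter had medians of 42025 UMIs and 7740.5 genes in the control library and 36696.5 UMIs and 7221.5 genes in the BMP4 library. Their median share of mitochondrial UMIs was 10.4% in both, although the labels' protocols describe nuclei. With no replicate in either group, the intervals given in brackets, all at 95%, hold counting error only, and "higher" and "lower" describe these libraries.

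The first comparison was of the cell populations in each library. SC-alpha-like cells, which express glucagon, made up 19.96% [18.7 to 21.3] of control cells (742 cells) and 28.7% [27.3 to 30.003] of BMP4 cells (1284 cells), a difference of 8.70 percentage points [6.85 to 10.6]. SC-beta-like cells, which express insulin, made up 11.7% [10.7 to 12.7] (434 cells) and 15.5% [14.4 to 16.6] (693 cells), a difference of 3.79 points [2.31 to 5.27]. SC-enterochromaffin-like cells, which express the serotonin-synthesis enzyme TPH1, were a smaller share of the BMP4 library, at 26.1% [24.7 to 27.5] (969 cells) against 19.5% [18.4 to 20.7] (874 cells), a difference of -6.56 points [-8.39 to -4.75]. Duct or pancreatic progenitor-like cells, named from genes such as SPP1 and CFTR, were also a smaller share, at 4.06% [3.45 to 4.75] in the control and 2.14% [1.74 to 2.61] in the BMP4 library.

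Delta-like cells, which express somatostatin, had a share of 1.18% in each library (44 and 53 cells). Epsilon-like cells, which express ghrelin, had 1.05% and 1.16% (39 and 52 cells), and proliferating-like cells, led by TOP2A and MKI67, 3.23% and 2.66% (120 and 119 cells). Among named cells only, the SC-alpha-like share was 29.7% against 40.5%, the SC-beta-like share 17.4% against 21.9% and the SC-enterochromaffin-like share 38.8% against 27.6%. No measured marker of SC-alpha, SC-beta, SC-enterochromaffin or proliferating cells was 1.5-fold apart between the libraries within its class. The SC-beta-like class consisted of clusters with 65.7% and 34.3% of its control cells and 65.8% and 34.2% of its BMP4 cells. Of the SC-alpha-like class, cluster 1 held 56.2% of control and 48.2% of BMP4 cells and cluster 4 held 25.3% and 34.0%. Of all analysed cells, cluster 4 held 5.06% in the control and 9.75% in the BMP4 library, the largest rise of the class. Cluster 1 held 11.2% and 13.8%, and cluster 8 held 3.68% and 5.09%. Cluster 4 took its name from 4 markers, 0 of them among its 10 leading genes. Its CHGA level was 3646 CPM, against 11208 in cluster 1 and 14022 in cluster 8. Under the filter first set for nuclei, the differences were 7.02 points for SC-alpha-like and 5.71 points for SC-beta-like cells. With no filter on barcodes, the SC-beta-like difference was -1.86 points.

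**Figure D1:**
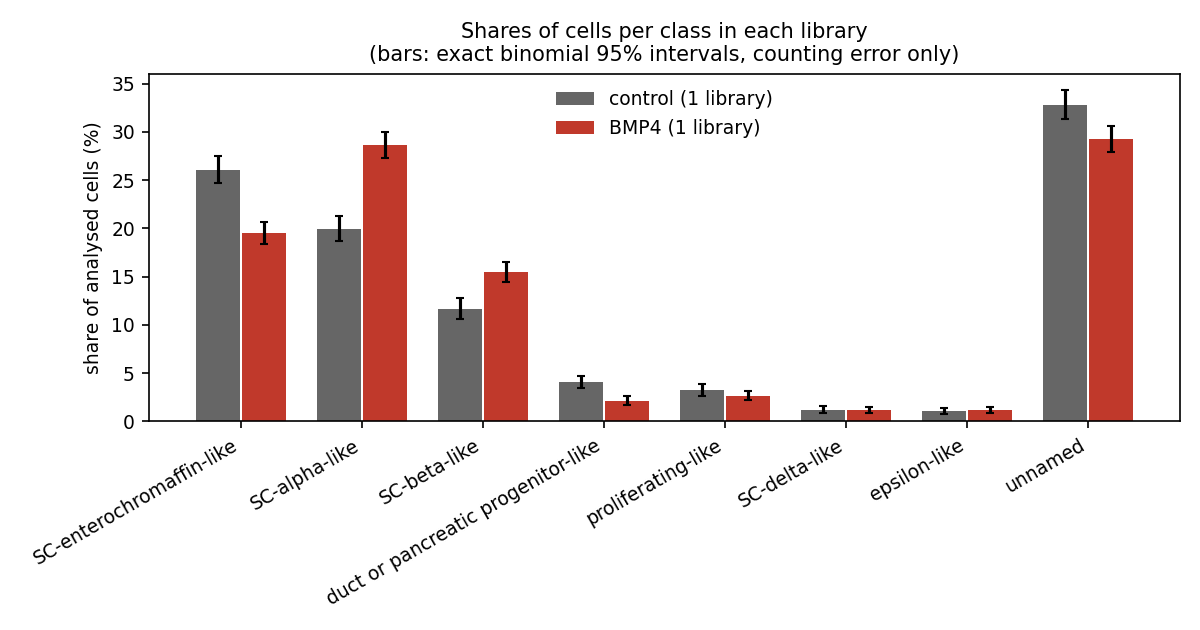
Share of analysed cells (%) in each class for the control and BMP4 libraries, with exact binomial 95% intervals for counting error as bars. SC-alpha-like cells stood at 19.96% in the control and 28.7% in the BMP4 library, and SC-enterochromaffin-like cells at 26.1% and 19.5%.

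BMP target genes, which SMAD proteins activate after BMP receptor signalling, were examined next because they bear on the labels. They were at similar levels in SC-beta-like cells of both libraries, and most were lower in SC-alpha-like cells of the library labelled BMP4. In SC-beta-like cells, ID1, an inhibitor of basic helix-loop-helix factors, stood at 21.5 CPM [19.6 to 23.5] in the control and 26.6 CPM [24.8 to 28.5] in the library labelled BMP4, a ratio of 1.24 [1.10 to 1.39]. SMAD9, a receptor-regulated SMAD, had a ratio of 1.27 [1.13 to 1.44], and SMAD7, an inhibitory SMAD, a ratio of 0.80 [0.71 to 0.92]. ID2 (1.08), ID4 (0.93) and ID3 (1.01, below 20 CPM) had intervals that included 1. In SC-alpha-like cells, ID1 had 57.0 CPM in the control and 46.3 CPM in the library labelled BMP4, a ratio of 0.81 [0.76 to 0.87]. The ratio there was 0.78 for ID4, while SMURF2 was higher at 1.12 [1.06 to 1.18]; ID3 and SMAD9, at 0.74 and 0.65, lay below 20 CPM. The summed UMIs of the listed target genes had ratios of 1.03 [0.998 to 1.06] in SC-beta-like, 0.91 [0.887 to 0.934] in SC-alpha-like and 1.03 [1.00 to 1.06] in SC-enterochromaffin-like cells. Other classes were not summed. In proliferating-like cells the median log2 ratio of 7 target genes was 0.16 [0.05 to 0.27]. Duct or pancreatic progenitor-like cells, too few to be compared, had ratios of 0.30 [0.22 to 0.40] for ID3 and 1.29 [1.15 to 1.45] for ID4. Without the top cells these were 0.35 and 0.96. ID1 in SC-beta-like cells kept its direction in 21 of 26 other settings. Its log2 ratio was -0.18 at 10% mitochondrial UMIs and -0.16 under the filter first set for nuclei. Target levels thus did not point the same way in these classes, and elsewhere "the BMP4 library" means the library labelled so.

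**Figure D2:**
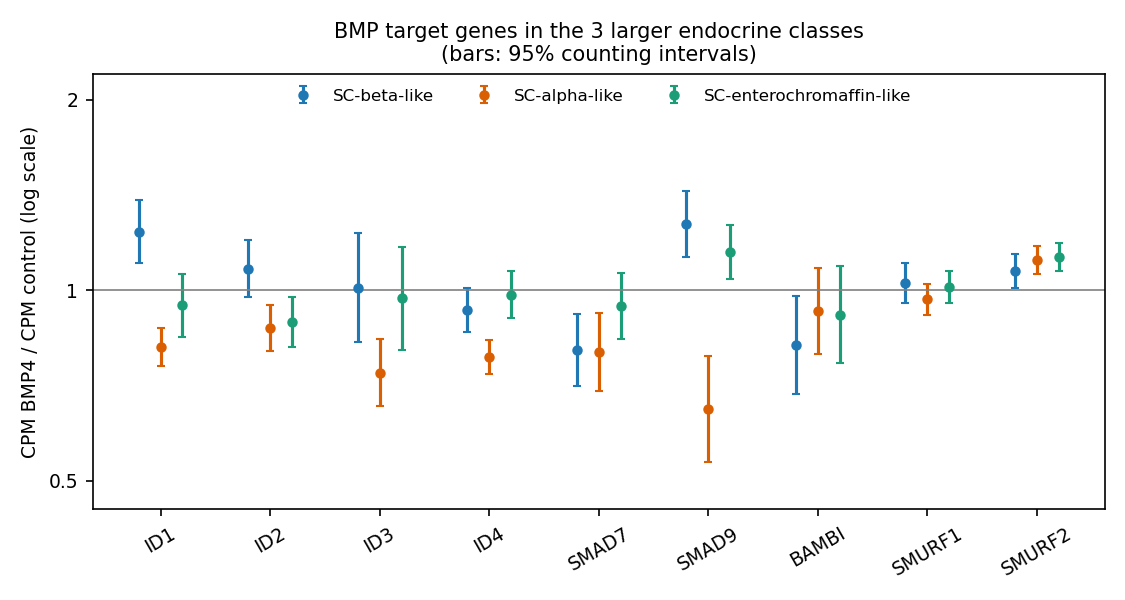
Ratio of CPM in the BMP4 library to CPM in the control library (log axis) for BMP target genes in 3 classes, with 95% counting intervals as bars. ID1 lay at 1.24 in SC-beta-like and 0.81 in SC-alpha-like cells.

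The comparison of control with BMP4-treated SC-beta cells is the one the study's design text states. The libraries were close to each other in these cells: of 7289 genes compared, 98.6% had the higher value less than 25% above the lower, 0 were 2-fold higher and 2 were 2-fold lower in the BMP4 library, all with 5 CPM added to both values. Without the added CPM, 1 was 2-fold higher and 3 lower. The genes 2-fold lower with it were MT2A, a metal-binding metallothionein, and COL5A2, a collagen gene and enterochromaffin marker at 6.87% of its level in SC-enterochromaffin-like cells, so free RNA can account for it. At 1.5-fold, also with 5 CPM added, 5 genes were higher and 9 lower, 7 of the 14 at levels that free RNA can give. This count of 14 was 6 with 20 CPM added and 96 of 2888 genes under the filter first set for nuclei. Insulin (INS; ENSG00000254647; chromosome 11, 2159779 to 2161341) made up 54060 CPM in the control and 60545 CPM in the BMP4 library, a ratio of 1.12 [1.117 to 1.123], and INS was the largest hormone count in 98.6% and 99.0% of the cells.

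The 12 highest log2 ratios in SC-beta-like cells belonged to genes of several kinds. RBFOX1, a splicing factor (ENSG00000078328; chromosome 16, 5239802 to 7713338), had 206 CPM [200.2 to 212] in the control and 326 CPM [320 to 333] in the BMP4 library, a ratio of 1.58 [1.53 to 1.64]. EBF1, a transcription factor, had 168 and 254 CPM, KLF6, a zinc-finger transcription factor, 58.0 and 86.7 CPM, and FOSB, a subunit of the AP-1 factor, 48.6 and 72.4 CPM. CRY1, a repressor of the circadian clock (ENSG00000008405; chromosome 12, 106991364 to 107093829), had 72.3 CPM [68.8 to 75.9] and 106 CPM [102 to 110], a ratio of 1.47 [1.38 to 1.56]. CCDC173 (ENSG00000154479; chromosome 2, 169645425 to 169694433) had 14.7 and 25.6 CPM, a ratio of 1.75 [1.53 to 2.00]. The ratio was 1.64 for MLF1, 1.51 for LRP2BP, 1.42 for TMEFF2 and 1.40 for TRPM3, a cation channel of beta cells. LRP1B, a member of the LDL receptor family, had a ratio of 1.45, but 1 cell gave 30.1% of its BMP4 UMIs, and without the top cell of each library the ratio was 1.13. NKAIN2, at 1.56, leads an SC-beta-like cluster and is not read as a result.

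The 12 lowest log2 ratios in SC-beta-like cells were also of mixed kinds. MT2A (ENSG00000125148; chromosome 16, 56608199 to 56609497) had 25.1 CPM [23.0 to 27.2] in the control and 6.67 CPM [5.77 to 7.66] in the BMP4 library, a ratio of 0.27 [0.23 to 0.31]. 1 cell gave 36.3% of its control UMIs, and without the top cells the ratio was 0.33. ANKS1B (ENSG00000185046; chromosome 12, 98726457 to 99984654) had 649 CPM [639 to 660] and 447 CPM [439 to 455], a ratio of 0.69 [0.67 to 0.70]. TM4SF4, a tetraspanin-like membrane protein and SC-alpha marker, had 113 and 77.8 CPM, and CD36, a fatty acid transporter, 51.9 and 35.7 CPM. NPNT, a matrix ligand of integrins, had 49.0 and 33.2 CPM, and CNTN3, a neural adhesion protein, 30.7 and 21.2 CPM. PDE10A, which degrades cyclic nucleotides, had 44.9 and 30.7 CPM. JUNB, another AP-1 subunit, had 82.4 and 58.2 CPM, the stress-factor gene HSF4 40.3 and 27.6 CPM, and CITED2, a transcriptional co-regulator, 22.3 and 15.1 CPM. The ratio was 0.63 for NKAIN3 and 0.70 for ADAMTSL4-AS1, an antisense gene whose reads cannot be told from its partner's without a stated strand setting.

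Random parts of 1 library gave a floor for these sizes. Over 20 splits, a median of 2 genes in control cells and 1 gene in BMP4 cells lay 2-fold apart, and 14.5 and 8.5 genes 1.5-fold apart. In draws of 217 cells from each library, the same number as in a part of the control cells, the libraries differed from each other by a median of 6 genes at 2-fold and 39 at 1.5-fold. The median size of the log2 ratio was 0.09 in these draws and 0.07 in the control splits. Under the filter first set for nuclei, 287 control and 438 BMP4 cells were SC-beta-like, 2888 genes were compared and 5 were 2-fold apart. There 14 of the 24 named genes had the opposite direction, among them RBFOX1, KLF6, CRY1, MT2A, ANKS1B and CD36. Most barcodes under that filter had under 2000 genes, so its values may not describe intact cells or nuclei. MALAT1, a nuclear RNA, gave 0.098% (control) and 0.081% (BMP4) of non-mitochondrial UMIs in barcodes with under 2000 genes and at most 2% mitochondrial UMIs. In the barcodes kept by the filter used it gave 1.67% in each library. Thinning the cells to 3000 UMIs kept the direction of all 24 genes. CCDC173, MLF1, FOSB, LRP2BP, NKAIN3, TM4SF4, HSF4 and CNTN3, 8 of the 24, kept their direction in every setting that gave a value.

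**Figure D3:**
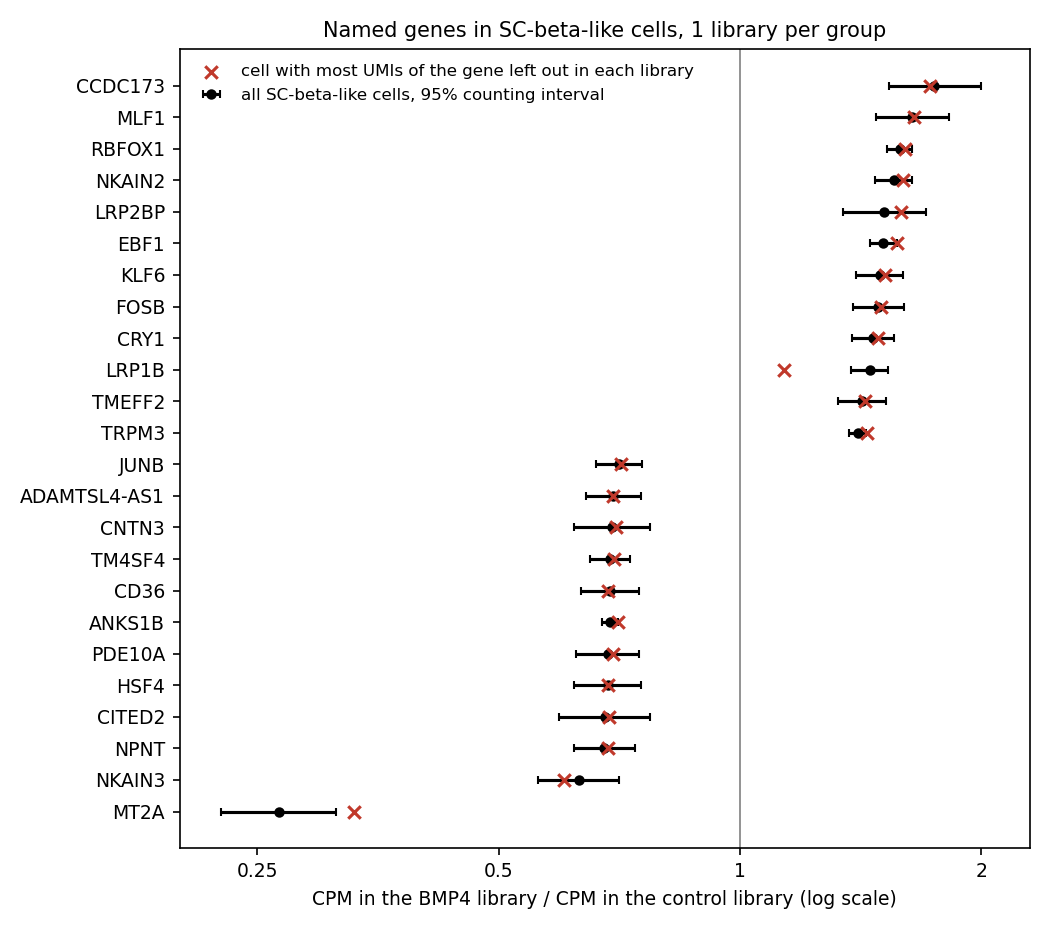
Ratio of CPM in the BMP4 library to CPM in the control library (log axis) for the 24 named genes in SC-beta-like cells, with 95% counting intervals as bars for all SC-beta-like cells and crosses for the ratio without the cell with most UMIs of the gene in each library. MT2A lay lowest at 0.27 and CCDC173 highest at 1.75, and 14 of the 24 genes had the opposite direction under the filter first set for nuclei.

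Gene lists in SC-beta-like cells differed by small amounts. Islet transcription factors had a median log2 ratio of -0.08 over 19 measured genes (percentile 0.25 among matched random lists), 15 of them below 0. NEUROD1, a driver of endocrine differentiation, had 221 and 180 CPM, and FOXA2 57.9 and 48.3 CPM. Nuclear genes of oxidative phosphorylation had a median of -0.09 (percentile 0.10), with 20 of 21 below 0, such as COX8A at 228 and 197 CPM. Glycolysis had a median of -0.12 over 11 genes (percentile 0.27), with LDHA, lactate dehydrogenase, at 44.1 and 36.6 CPM. No member of these lists was 1.5-fold apart. BMP target genes had a median of 0.09 over 7 genes (percentile 99.2), and -0.16 under the filter first set for nuclei; in SC-alpha-like cells it was -0.17 [-0.26 to -0.08] over 5 genes, 4 of them below 0 (percentile 0.06). Under that filter the medians were 0.05 for glycolysis, -0.0061 for oxidative phosphorylation (nuclear genes) and -0.025 for islet transcription factors.

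Lists of functional genes of beta cells had medians near 0 with the filter used. Beta cell maturation had a median of -0.02 over 11 genes (percentile 32.0), with the glucose-6-phosphatase G6PC2 at 61.6 and 48.2 CPM and the hormone IAPP at 3064 and 3371 CPM. Insulin secretion and exocytosis had a median of -0.00 over 26 genes (percentile 36.9), with the glucose transporter SLC2A2 at 31.5 and 41.3 CPM and the granule protein CHGA at 9687 and 7968 CPM. Ion channels and calcium handling had 0.02 over 26 genes (percentile 92.5), with the calcium store receptor ITPR3 at 25.3 and 20.1 CPM and the calcium channel CACNA1E, which leads an SC-beta-like cluster, at 136 and 168 CPM. Incretin and cAMP signalling had -0.00 over 14 genes (percentile 51.2), with the incretin receptor GLP1R at 35.2 and 38.4 CPM. BMP pathway components had -0.00 over 9 genes, with the receptor ACVR1 at 114 and 127 CPM. The medians for maturation, secretion, incretin signalling and BMP pathway components were above 0 under TMM and median of ratios scaling, which moved all genes by 0.04. Under the filter first set for nuclei the medians were 0.25 for ion channels and calcium handling, 0.26 for incretin and cAMP signalling, 0.25 for BMP pathway components, 0.063 for insulin secretion and exocytosis and 0.017 for beta cell maturation. With no filter, the beta cell maturation median was 0.12.

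Medians of the stress, signalling and other lists were also within 1.5-fold, as were their measured members except FEV. Unfolded protein and stress response had a median of -0.04 over 14 genes, with the kinase EIF2AK3 at 87.9 and 117 CPM and the stress factor ATF3 at 19.99 and 28.4 CPM. Immediate early genes had -0.07 over 9 genes, with FOSB higher and JUNB lower as above and FOS at 275 and 246 CPM. Hypoxia genes had -0.07 over 6 genes, cholesterol synthesis -0.06 over 13, proliferation -0.12 over 4, and extracellular matrix and integrins -0.03 over 8. Notch and progenitor genes had -0.04 over 3 genes, Wnt targets 0.05 over 2 and TGF-beta and activin targets -0.15 over 2. Other endocrine hormones and regulators had -0.10 over 7 genes (percentile 1.38). The enterochromaffin regulator FEV stood at 62.2 and 29.6 CPM there, but at 8.61% of its level in SC-enterochromaffin-like cells, which free RNA can give. Under the filter first set for nuclei, the medians above 0 were 0.11 for immediate early genes, 0.15 for TGF-beta and activin target genes, 0.071 for cholesterol synthesis, 0.034 for Notch and progenitor genes, 0.010 for unfolded protein and stress response and 0.0092 for other endocrine hormones and regulators. In SC-beta cluster 7 alone, immediate early genes had 0.19.

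**Figure D4:**
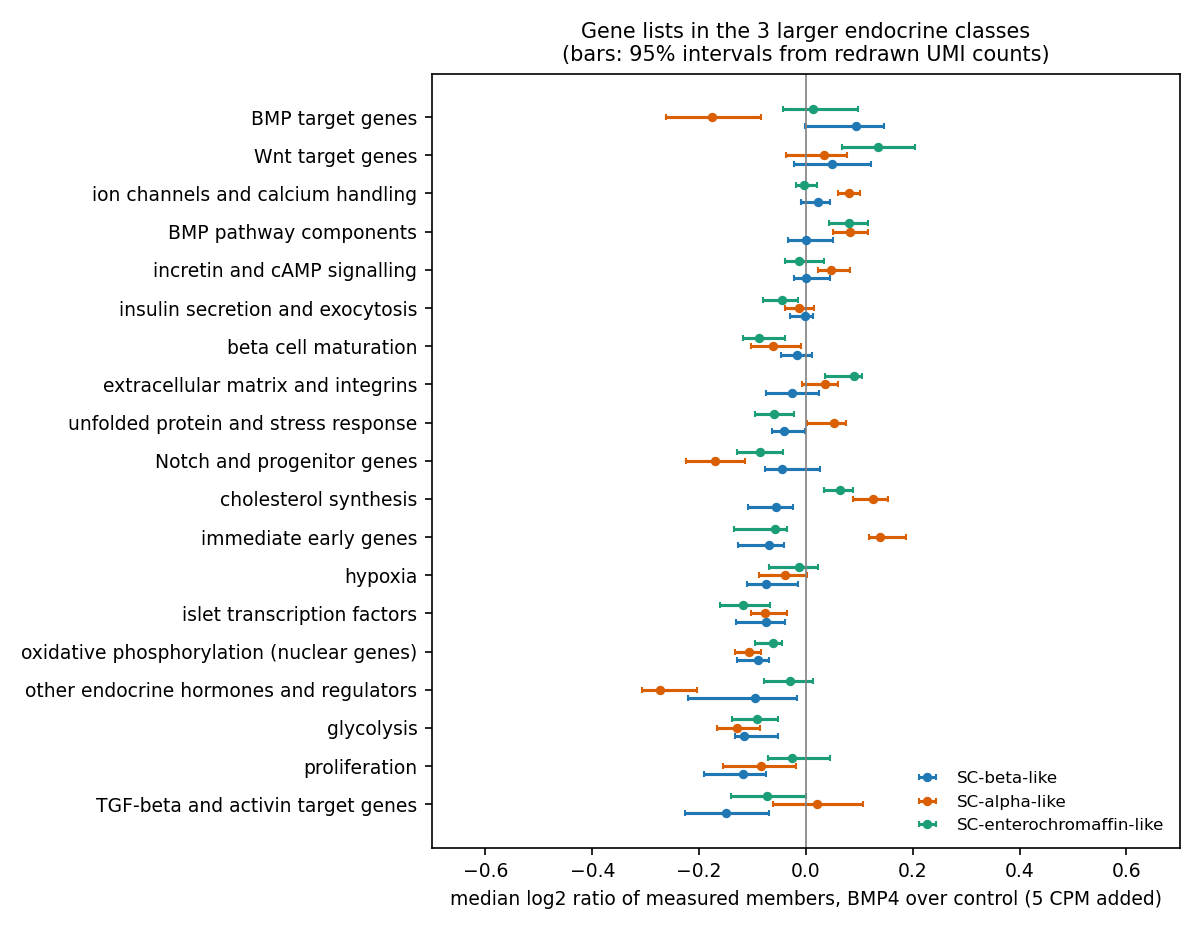
Median log2 ratio (BMP4 over control, 5 CPM added) of each gene list in 3 classes, with 95% intervals from redrawn UMI counts as bars. Medians of oxidative phosphorylation and glycolysis lie below 0 in each class, and in SC-beta-like cells glycolysis lies at 0.05 under the filter first set for nuclei.

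In the other classes, partly the same genes stood apart. In SC-alpha-like cells, 7503 genes were compared, and the stress-responsive factor ATF3, at 9.45 and 24.2 CPM, was the 1 gene 2-fold higher in the BMP4 library with 5 CPM added. Without the added CPM, 3 were 2-fold higher and 3 lower. LRP2BP (12.99 and 28.1 CPM), MLF1 (27.4 and 53.1 CPM) and YPEL5 (94.2 and 172 CPM) were the next highest. LRP1B, at 432 and 237 CPM, ZNF804A, at 49.9 and 32.3 CPM, and the metallothionein MT1X, at 44.3 and 28.9 CPM, were lower. TFPI2, at a ratio of 0.50, leads an SC-alpha-like cluster and is not read as a result. Somatostatin (SST) was the 1 gene 2-fold lower with 5 CPM added, at a level free RNA can give (304.8 and 66.65 CPM). From control to BMP4, SST also fell in SC-enterochromaffin-like cells (406.5 to 163.9 CPM) but rose in SC-beta-like cells (305.6 to 399.9 CPM). Its level alone thus does not show free RNA as the source, which was not tested. Immediate early genes had a median of 0.14 over 10 genes (percentile 99.8), cholesterol synthesis 0.13 over 13 (percentile 99.7), oxidative phosphorylation -0.11 over 21 (percentile 0) and glycolysis -0.13 over 11 (percentile 0.33). The mix of clusters in the SC-alpha-like class differed between the libraries. A change in that mix was not separated from a change within the cells.

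In SC-enterochromaffin-like cells, 7593 genes were compared, and the 3 that lay 2-fold apart with 5 CPM added, GCG, CNTN4 and SST, were at levels free RNA can give. Without the added CPM, 6 were 2-fold higher and 1 lower. LRP2BP (13.3 and 27.5 CPM), the myosin gene MYO1E (15.3 and 28.9 CPM), the ribosome biogenesis gene RRP12 (20.9 and 37.7 CPM) and PID1 (12.4 and 22.3 CPM) were the highest of the named genes. IFI6, an interferon-induced gene, had 138 and 94.1 CPM, the G protein subunit gene GNG3 32.0 and 21.2 CPM, and the histone genes HIST1H2BE and HIST1H2AC had ratios of 0.66 and 0.71. Islet transcription factors had a median of -0.12 over 19 genes (percentile 0).

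In proliferating-like cells, 8206 genes were compared, 5 were 2-fold higher and 10 lower in the BMP4 library with 5 CPM added (12 and 18 without it), but single cells carried much of these differences. CGA, the glycoprotein hormone alpha subunit, had 95.7% of its BMP4 UMIs in 1 cell, and its ratio of 40.5 was 3.17 without the top cells. ITM2A went from 3.05 to 1.42 in this way, the neurofilament gene NEFL from 2.83 to 2.26 and the transcription factor NFIA from 2.74 to 2.16. The ratio without the top cells was 0.27 for CSMD3, 0.37 for the potassium channel partner KCNIP4, 0.46 for CHSY3 and 0.43 for the estrogen receptor ESR1. In the control library CSMD3, KCNIP4 and ESR1 were highest in SC-enterochromaffin-like cells, and CHSY3 was among the leading genes of a cluster of that class. A change in the mix of proliferating-like cells was therefore not separated from a change within them. Across the 6842 genes measured in both, 68.4% had the same sign in SC-beta-like and SC-alpha-like cells, with a Pearson correlation across genes of 0.51, where genes are not independent replicates. The same values were 65.6% and 0.38 for SC-enterochromaffin-like cells and 62.4% and 0.33 for proliferating-like cells. In 20 random splits of the control cells, a median of 50.7% of genes, and at most 55.5%, had the same sign in SC-beta-like and SC-alpha-like cells. In such splits at most 53.4% had the same sign for SC-enterochromaffin-like and 58.7% for proliferating-like cells, where the correlation reached 0.20. Each class was split on its own within 1 library, so unrelated signs were built in. The splits hold no difference between libraries and cannot tell BMP4 from any other difference that the classes of a library share. Differences between the classes were not tested.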

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

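The differences between classes given here were found in these libraries and chosen after their values were seen, by a bound of 0.5 on the log2 scale in each direction; none was tested. LRP1B was higher in SC-beta-like cells of the BMP4 library, with a log2 ratio of 0.52, and lower in SC-alpha-like cells (-0.85) and in proliferating-like cells (-0.96). In SC-beta-like cells 1 cell gave 30.1% of its BMP4 UMIs, and without the top cells its ratio there was 1.13. Within the SC-alpha-like class, its ratio was 0.56 [0.545 to 0.579] in cluster 1, 1.97 [1.53 to 2.57] in cluster 4 and 0.98 [0.908 to 1.06] in cluster 8, and cluster 1 held 56.2% of that class in the control and 48.2% in the BMP4 library. RBFOX1 was higher in SC-beta-like cells (0.65) and lower in proliferating-like cells (-0.97). In SC-beta-like cells RBFOX1 kept its direction in 22 of 26 other settings, with a lowest log2 ratio of -0.29, and LRP1B in 21 of 26, with a lowest of -0.81 when each library was clustered on its own. The proliferating-like cells also differed in markers of other classes: from control to BMP4, TPH1 went from 417 to 241 CPM, FEV from 361 to 206, SST from 6969 to 2987 and GCG from 3875 to 6704. RBFOX1 and LRP1B were highest in SC-enterochromaffin-like cells, so a change in the mix of proliferating-like cells was not separated from a change within them. MT1X was lower in SC-alpha-like cells (-0.54) and higher in proliferating-like cells (0.79). KCNIP4, which leads an SC-enterochromaffin-like cluster, was higher in that class (0.51) and lower in proliferating-like cells (-1.75), where 1 cell gave 42.9% of its control UMIs.

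Barcodes with over 80% mitochondrial UMIs lay outside the comparisons, except in the setting with no filter. They were a larger share of the BMP4 library, 22.4% [21.6 to 23.3] of its barcodes against 18.4% [17.5 to 19.4] in the control. They were listed because their share in the BMP4 library was above that in the control library. Their median UMI counts were 4044 and 3991.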

How the results depend on the processing

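The filters at 10% and 30% mitochondrial UMIs and at 500 genes with 20%, the clusters taken alone, the added INS-rich cluster, the totals without mitochondrial genes and the top cells left out were chosen after the data were seen; the other settings were fixed before. No paired analysis was possible because each group has 1 library and no result comes from a test. A value counts as reversed where its interval lay to one side of 0 and it fell on the other side. Of 832 named-gene values, 579 moved by less than their counting interval, 217 moved by more and 36 reversed; of 473 list medians these numbers were 349, 106 and 18, and of 49 share differences 38, 10 and 1. Of 50 counts of SC-beta-like genes apart by 2-fold or 1.5-fold, 27 were within 1.5 times the reported count. Depth and the added CPM limit what small ratios can show. The cause was not tested where none is given.

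Under the filter first set for nuclei, 5 SC-beta-like genes lay 2-fold apart and the SC-beta-like difference was 5.71 points. The list medians were -0.16 for BMP target genes, 0.25 for BMP pathway components, -0.025 for islet transcription factors, 0.017 for beta cell maturation, 0.063 for insulin secretion and exocytosis, 0.25 for ion channels and calcium handling, 0.26 for incretin and cAMP signalling, -0.0061 for oxidative phosphorylation (nuclear genes), 0.048 for glycolysis, 0.010 for unfolded protein and stress response, 0.11 for immediate early genes, -0.13 for hypoxia, 0.034 for Notch and progenitor genes, 0.15 for TGF-beta and activin target genes, -0.19 for extracellular matrix and integrins, -0.23 for proliferation, 0.0092 for other endocrine hormones and regulators and 0.071 for cholesterol synthesis; those of glycolysis, stress response, immediate early, TGF-beta, other endocrine and cholesterol genes reversed. The log2 ratios that reversed there were RBFOX1 -0.29, NKAIN2 -0.50, KLF6 -0.023, CRY1 -0.24, LRP1B -0.63, TRPM3 -1.37, MT2A 1.36, ANKS1B 0.065, NPNT 0.29, CD36 0.79, PDE10A 0.22, ADAMTSL4-AS1 0.59, JUNB 0.13, CITED2 0.14, ID1 -0.16, SMAD7 0.48 and SMURF2 -0.24. That filter left 908052 and 1198866 SC-beta-like UMIs. At 2000 genes and 1% mitochondrial UMIs 60 control and 41 BMP4 cells remained, no SC-beta-like class could be named, so its genes and lists have no value, and the SC-alpha-like difference was 1.59 points.

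With no filter, 1 gene was 2-fold apart, RBFOX1 was -0.27, LRP1B -0.37, CD36 0.044 and ID1 -0.0071, and the differences were -1.86 points for SC-beta-like and 5.26 for SC-alpha-like cells. Medians were 0.12 for beta cell maturation, 0.021 for unfolded protein and stress response, -0.0094 for hypoxia, -0.049 for TGF-beta and activin target genes, 0.027 for extracellular matrix and integrins and -0.23 for other endocrine hormones and regulators. At 10% mitochondrial UMIs the values were 1 gene, TMEFF2 -0.20, ID1 -0.18, 11.3 points for SC-alpha-like and -3.91 for duct or pancreatic progenitor-like cells. Medians were 0.066 for BMP pathway components, -0.033 for islet transcription factors, -0.049 for insulin secretion and exocytosis, 0.075 for incretin and cAMP signalling, -0.0059 for immediate early genes, -0.12 for hypoxia, -0.17 for Notch and progenitor genes, 0.17 for Wnt target genes, -0.29 for TGF-beta and activin target genes, -0.13 for extracellular matrix and integrins, 0.0025 for other endocrine hormones and regulators and -0.13 for cholesterol synthesis. At 30% there was 1 gene, LRP1B was -0.21, and medians were 0.013 for beta cell maturation, -0.058 for Wnt target genes and -0.29 for other endocrine hormones and regulators. At 500 genes with 20%, TMEFF2 was -0.062 and ID1 -0.0019, and medians were 0.053 for BMP pathway components, 0.030 for beta cell maturation, 0.062 for incretin and cAMP signalling, -0.14 for glycolysis, 0.011 for unfolded protein and stress response, -0.040 for immediate early genes, -0.20 for proliferation and -0.39 for other endocrine hormones and regulators.

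Doublets at the automatic threshold gave an SC-alpha-like difference of 3.86 points and resolution 2 gave 3.99 points, because part of the class was named PP there; both together differed by 7.28 and 7.499 points. Medians at resolution 2 were -0.13 for Notch and progenitor genes, -0.028 for Wnt target genes and -0.011 for cholesterol synthesis. No centring gave 1 gene and -8.42 points for SC-enterochromaffin-like cells, with -0.048 for beta cell maturation, -0.028 for incretin and cAMP signalling, -0.064 for oxidative phosphorylation (nuclear genes), -0.035 for immediate early genes and 0.0015 for proliferation. Each library clustered on its own gave 9 genes, LRP1B -0.81, TMEFF2 -0.50, PDE10A 0.22, 1.07 points for SC-beta-like and 12.5 for SC-alpha-like cells. Its medians were 0.016 for insulin secretion and exocytosis, 0.052 for ion channels and calcium handling, -0.039 for incretin and cAMP signalling, -0.040 for oxidative phosphorylation (nuclear genes), -0.016 for glycolysis, 0.062 for unfolded protein and stress response, -0.14 for immediate early genes, 0.0077 for hypoxia, 0.072 for Notch and progenitor genes, -0.22 for Wnt target genes, -0.060 for TGF-beta and activin target genes, -0.15 for extracellular matrix and integrins, -0.043 for proliferation and -0.63 for other endocrine hormones and regulators. Cells with INS as the largest hormone count gave -0.26 for other endocrine hormones and regulators, and the mean over cells -0.0064 for immediate early genes.

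TMM scaling gave -0.038 for islet transcription factors, 0.022 for beta cell maturation, 0.037 for insulin secretion and exocytosis, 0.060 for ion channels and calcium handling, -0.052 for oxidative phosphorylation (nuclear genes), -0.031 for immediate early genes and -0.018 for cholesterol synthesis, and median of ratios scaling -0.037 for islet transcription factors, 0.023 for beta cell maturation, 0.038 for insulin secretion and exocytosis, 0.061 for ion channels and calcium handling, -0.050 for oxidative phosphorylation (nuclear genes), -0.00045 for unfolded protein and stress response, -0.029 for immediate early genes and -0.017 for cholesterol synthesis. Thinning to 3000 UMIs gave 4 genes and SMURF2 -0.078, with 0.18 for BMP target genes, 0.060 for BMP pathway components, -0.14 for oxidative phosphorylation (nuclear genes), -0.036 for glycolysis, 0.052 for unfolded protein and stress response, 0.057 for immediate early genes, -0.15 for hypoxia, -0.083 for Notch and progenitor genes, -0.066 for Wnt target genes, 0.030 for TGF-beta and activin target genes, 0.14 for extracellular matrix and integrins and -0.075 for proliferation. Adding 20 CPM gave 0 genes. A minimum of 5 CPM gave -0.048 for Wnt target genes and -0.28 for other endocrine hormones and regulators; one of 50 CPM gave 1 gene, 0.028 for extracellular matrix and integrins and -0.20 for proliferation.

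SC-beta cluster 3 alone gave 1 gene and -0.21 for immediate early genes. Cluster 7 alone gave 13 genes, RBFOX1 -0.036, EBF1 -0.12 and CD36 0.17, with medians of -0.21 for islet transcription factors, -0.060 for beta cell maturation, -0.030 for ion channels and calcium handling, -0.080 for incretin and cAMP signalling, -0.15 for oxidative phosphorylation (nuclear genes), -0.19 for glycolysis, 0.082 for unfolded protein and stress response, 0.19 for immediate early genes, -0.16 for hypoxia, -0.18 for Notch and progenitor genes, -0.090 for extracellular matrix and integrins and -0.28 for other endocrine hormones and regulators. With the INS-rich unnamed cluster added there were 0 genes, RBFOX1 was -0.039, LRP1B -0.15 and ID1 -0.012, and medians were 0.065 for BMP pathway components, -0.021 for islet transcription factors, 0.079 for beta cell maturation, 0.059 for ion channels and calcium handling, -0.13 for oxidative phosphorylation (nuclear genes), 0.00029 for unfolded protein and stress response, -0.0088 for hypoxia, 0.051 for extracellular matrix and integrins and -0.30 for other endocrine hormones and regulators.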

Other observations

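Some clusters that took no cell class name carried genes of their own, while clusters 2, 5 and 10 had 0 genes 1.5-fold above every other cluster. Cluster 9 was led by EYA2, a developmental transcriptional co-activator, COL4A2, a basement membrane collagen, the BMP receptor gene BMPR1B and the Wnt receptor gene ROR2, and held 137 control and 175 BMP4 cells. Cluster 14 held 62 control and 100 BMP4 cells, which did not share its leading genes: CLPS, which encodes a pancreatic digestive protein, had 2467 UMIs in its control and 0 in its BMP4 cells, and the collagen gene COL3A1 255 and 2. Cluster 20, led by GUCA2B, AFP, AGR2 and APOA4, genes of gut or liver epithelium, held 27 and 14 cells. Cluster 19, with 33 and 47 cells, was led by the growth factor gene AREG, with 154 and 255 CPM, and the heat shock gene HSPA6, with 0 and 304 UMIs. Cluster 15, with 72 and 67 cells, was led by the gastrin gene GAST, with 46 and 0 UMIs, and by ribosomal protein genes, and its cells had a median of 7526 UMIs and of 0.607% mitochondrial UMIs. In SC-enterochromaffin-like cells, GCG had 238 CPM in the control and 596 CPM in the BMP4 library, a level free RNA can give.

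Of the tests below, those on the clock genes and on the CREB target genes were fixed before their values were seen, while the comparison of CREB targets with the shared genes and the other tests were chosen after the results they measure had been seen. BMP target genes at like levels in both libraries were the first pattern examined. Too few UMIs are argued against, since the upper bound of the summed ratio in SC-beta-like cells was 1.06, below a 2-fold rise. A swap of the library labels stays open. The ratio was summed in SC-beta-like, SC-alpha-like and SC-enterochromaffin-like cells only. It was 0.91 in SC-alpha-like cells, and the intervals of these classes did not all lie to the same side of 1, a bound set after the values were known. A return of target levels to baseline within 11 days may also give this pattern; that was not tested, and neither was any other difference between the cultures.

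A set of genes was higher in the BMP4 library in all 4 compared classes. Of the 21 genes named among the highest of any class, 8 had intervals above 1 in each: LRP2BP, MLF1, YPEL5, KLF6, FOSB, CRY1, MYO1E and RRP12. Of the 24 named among the lowest, 4 had intervals below 1 in each: TM4SF4, JUNB, IFI6 and HIST1H2AC. CRY1, for example, had ratios of 1.47 in SC-beta-like, 1.69 in SC-alpha-like, 1.45 in SC-enterochromaffin-like and 1.64 in proliferating-like cells. Under the filter first set for nuclei, the log2 ratios of KLF6 (-0.023), CRY1 (-0.24) and JUNB (0.13) in SC-beta-like cells had the opposite direction. The directions of YPEL5, MYO1E, RRP12, IFI6 and HIST1H2AC were not checked under other settings, nor were those of any of these genes in the other classes.

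For this set, free RNA from another class is argued against for the 8 higher genes in the larger endocrine classes. Their rises would need a share of the level of the named class where each was otherwise highest. The median share was 15.9% in SC-beta-like, 55.1% in SC-alpha-like and 18.5% in SC-enterochromaffin-like cells. Each gene needed more than the 5 most abundant markers of that class rose (at most 0.688%, 3.06% and 2.96%). The naming rule had left out genes under 10% of their level in the class where they were highest. Free RNA can give such levels, so this result was in part built in and covers these 8 genes only. In proliferating-like cells, with a median of 29.4%, free RNA stays open, because GCG rose by 21.7% and 5 of the 8 genes needed more. Immediate early genes rising together are argued against as the whole cause in SC-beta-like and SC-enterochromaffin-like cells. Their median log2 ratios there were -0.070 (SD 0.28, 6 of 9 below 0, percentile 6.35) and -0.06 (SD 0.23, 9 of 10 below 0, percentile 6.26). JUNB was also among the lower genes. In SC-alpha-like and proliferating-like cells this explanation also stays open, with medians of 0.14 (SD 0.29, percentile 99.8) and 0.08 (SD 0.34, percentile 92.6). The 8 higher genes had medians of 0.51, 0.78, 0.49 and 0.67 in SC-beta-like, SC-alpha-like, SC-enterochromaffin-like and proliferating-like cells. They were picked for high ratios, so a list median below theirs decides nothing. An immediate early response to handling as a part of the pattern stays open. The test first set for it found 0% of them 1.5-fold higher in SC-beta-like cells. It used a bar that only 1 of the 8 genes reached. A different phase of the circadian clock stays open. Of the listed clock genes, 0 were 25% or more higher in the same library in both SC-beta-like and SC-alpha-like cells. That list held only genes whose values had not been seen, so it left out CRY1, and 6 and 9 of its 16 members were measured. Medians were 0.03 (percentile 85.1) and 0.06 (percentile 84.1), and 0.01 (percentile 73.4) in SC-enterochromaffin-like cells. NR1D2 came nearest, at 1.16 [1.10 to 1.22] and 1.36 [1.30 to 1.42], and had 1.11 [1.07 to 1.16] in SC-enterochromaffin-like cells. The listed CREB target genes did not rise together in SC-beta-like and SC-alpha-like cells, where their medians lay at percentiles 18.1 and 46.5. In SC-enterochromaffin-like cells the median of 0.12 lay at percentile 99.9. Their highest log2 ratios were 0.11, 0.13 and 0.18 in these classes, against medians of 0.51, 0.78 and 0.49 of the 8 higher genes. Those 8 genes were picked for high ratios, so this comparison decides nothing. The list held only genes whose values had not been seen, and 7, 5 and 7 of its 18 members were measured. A CREB response as a cause of the pattern therefore stays open. A difference in culture or handling that came with the libraries might also raise these genes, and it cannot be separated from BMP4 with 1 library per group.

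The larger share of SC-alpha-like and smaller share of SC-enterochromaffin-like cells in the BMP4 library was the last pattern weighed. The choice of filter is argued against, since the smallest SC-alpha-like difference over the other filters that keep 1000 or more cells per library was 5.26 points [4.04 to 6.47]; the filter first set for nuclei, with fewer control cells, gave 7.02 points. The doublet-like unnamed clusters 2, 5, 10 and 16, the last with 1 gene 1.5-fold above every other cluster, held 23.9% of control and 20.2% of BMP4 cells. Without them the difference was 9.71 points [7.43 to 12.0]. Leaving them out changed only the totals, not the number of SC-alpha-like cells, so this cannot decide whether cells hidden in them matter. That explanation stays open. An effect of BMP4 on the balance of these cell types is a hypothesis that these libraries could not separate from variation between batches of organoids, which was not tested.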
